A study of Oryza sativa with 24 samples.

How the data were processed

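The samples were rice (Oryza sativa) seedlings grown, per the labels' protocols, in Yoshida's nutrient solution under 13 h of light at 26 °C and 11 h of dark at 22 °C and treated with 15% PEG6000. Per the labels, small RNA libraries were amplified by PCR with a Cy5-labelled primer and hybridized to spotted arrays in 1 colour. The series' design gives 2 libraries per time point as biological replications and 2 hybridizations of each as technical ones. It does not say whether the libraries came from separate plants or pools, so the p-values measure the spread between libraries, which may be partly technical. Every sample belongs to the PEG series, 0 h is the untreated state, and seedlings kept without PEG for the same times were not analysed here.

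Per the file headers, the spots were measured with a fixed circle and the deposited scanner values are spot intensity and local background on a linear scale, neither crosstalk corrected nor background subtracted. The authors' deposited series table holds intensity minus background of the same spots, which was checked spot by spot (largest difference 9e-06); no scaling between arrays was found in it. Other steps of the authors' processing are not given in the sources used here. Local background was recorded as 0 for nearly all spots, with 83 spots above 0 over the 24 arrays, at most 34 on 1 array. The planned filter on dim spots (intensity above background plus 2 SD of background) therefore removed no spot: all 896 spots of each array passed. For that reason a number of detected miRNAs per time point is not reported, and all 224 sets were tested. Signal over background cannot be judged from these files, although the 5th percentile of intensity differed between arrays (11.3 to 194).

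Each array's spot intensities were background corrected with normexp (offset 50), log2 transformed and quantile normalized, and the 4 spots of a set and then the 2 hybridizations of a library were averaged. The files give probe code R105 at 2 places, which are not known to hold 1 probe and were kept as 2 sets. limma 3.58.1 in R 4.3.3 fitted all 12 libraries with the time point as a factor (6 residual degrees of freedom; statmod 1.5.0 for random blocks). The contrasts were each later time minus 0 h and the mean of the late times minus the mean of the early times, with a moderated F test over the 5 contrasts against 0 h. Benjamini-Hochberg adjustment ran over the 224 sets of a contrast, and a set was said to have changed at an adjusted p under 0.05. All tests are two-sided. The standard errors are limma's moderated ones.

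The rule for naming sets, the tests and most alternatives were fixed before the data were examined. The rule took, in each comparison, the sets past the threshold whose libraries did not overlap between the groups, ordered by log2 change, plus the 10 sets with the smallest p in the F test. Because the codes have no names here, it was limited to the first 2 in each direction, and sets below the threshold were not listed where few passed. Lists of miRNA families, of miRNAs by function and of control probes had been planned too. None could be run, because the files do not pair codes with names, and the miR169 and miR393 families planned for separate report are not reported. The meaning of the letters in the codes is not given in the sources used here. The files' scan records give no batch that holds more than 1 array, so no block for slide or scan was fitted.

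The library numbers pair samples across time points by a check of the data: the difference between library 1 and library 2, taken over all sets, correlated between all 15 pairs of time points (0.478 to 0.764). The labels do not say what libraries of 1 number share. A second fit with the library number as a block (5 residual degrees of freedom) is given beside the counts it changed. The median fitted SD was 0.22 without the block and 0.17 with it on the log2 scale.

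The fit was tested on simulated data for 24 h minus 0 h, with the real means of the 224 sets and 40 sets changed, over 50 simulations. Each set was given its mean library difference, the same at all times. Independent normal noise was added with the SD of the fit with the block, and normalization was not rerun. This setting favours the fit with the block, so the shares below are not error rates of the real calls. Without the block 65.9% of the sets changed by 1 on the log2 scale and 93.4% of those changed by 2 were called, and 0.748% of calls were false. With the block these were 94.2%, 99.9% and 5.36%. Alternatives covered the background correction, the scaling, the average over spots, the use of single hybridizations or of all 24 with the library as a random block (consensus correlation 0.30), the libraries in the fit, the moderation, the deposited table and each library left out in turn. Cyclic loess, the brighter 112 sets, leaving out spots flagged by the scanner software and a block combined with all 24 hybridizations were added after the data had been seen, as were the comparison with separate 0 h libraries and all splits fitted with 1 group term, over drawn splits and over those balanced in library number.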

Results

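Rice seedlings were kept in a solution with 15% PEG6000, a polymer that holds water outside the root and so exposes the plant to osmotic stress, and small RNAs were profiled on spotted 1-colour arrays after 0, 0.5, 2, 6, 24 and 48 h. Each of the 6 time points was covered by 2 small RNA libraries, and each library was hybridized on 2 arrays, which gave 24 arrays from 12 libraries. The library was taken as the replicate (n = 2 per time point), and the values of its 2 hybridizations were averaged. Each array held 896 spots, which formed 224 sets of 4 spots under 223 probe codes. The deposited files give the codes only and do not pair them with miRNA names, so changes are reported for spot sets, at most 2 that rose and 2 that fell in a comparison. The median spot intensity of an array lay between 152 and 566, and 5 to 25 spots per array were above 60000, close to the scanner's ceiling. The number of libraries limits the precision of every comparison.

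The hybridizations of a library correlated over spot sets with a median r of 0.987 (0.971 to 0.993), and the libraries of a time point with a median r of 0.986 (0.980 to 0.989). Libraries of the same number at different times correlated as highly, with a median r of 0.987 (0.972 to 0.996). Those of different number at different times had a median r of 0.976 (0.963 to 0.987). The r within a time point is therefore no measure of how well a time point repeats. These are correlations across spot sets, which are not independent replicates. The median SD between the hybridizations of a library was 0.15 on the log2 scale, and that between the libraries of a time point was 0.16. The first was taken on single arrays and the second on values averaged over 2 hybridizations, so they cannot be compared directly. Over the treatment the median log2 change of all 224 sets against 0 h lay between -0.08 and 0.00 after quantile normalization. That step gives all arrays the same distribution, so a median near 0 was built in. Without normalization it lay between 0.04 (24 h) and 0.20 (48 h).

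The first comparison asked which small RNAs differed from the untreated state at 0.5 h. Spot set R220 rose from 8.16 ± 0.09 to 12.07 ± 0.33 (log2 intensity, SD, n = 2), a log2 change of 3.91 with a standard error of 0.33 and a fold of 15.0 (adjusted p = 0.00029). Set N9 rose to 8.20 ± 0.54, with a fitted log2 change of 1.99 (1.61 to 2.37 over the alternatives; adjusted p = 0.0376). Its 0 h level was near the floor of the arrays (mean raw intensity 46.6, median rank 216 of 224, below the offset of 50), so the size of its changes is not resolved. Set R224 fell by 2.43 ± 0.49 (SE), from 11.65 ± 0.47 to 9.22 ± 0.65 (adjusted p = 0.0376). In all, 6 of 224 sets changed, of which 5 rose and 1 fell, and 20 had an unadjusted p under 0.05. With the library number as a block, 15 sets changed (10 rose and 5 fell), with all 6 among them. Without library 1 of 0 h, library 1 of 0.5 h or library 2 of 0.5 h the count was 3, and N9 and R224 missed the threshold when any 1 of the 4 libraries compared was left out (adjusted p up to 0.282 for N9 and up to 0.257 for R224).

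**Figure D1:**
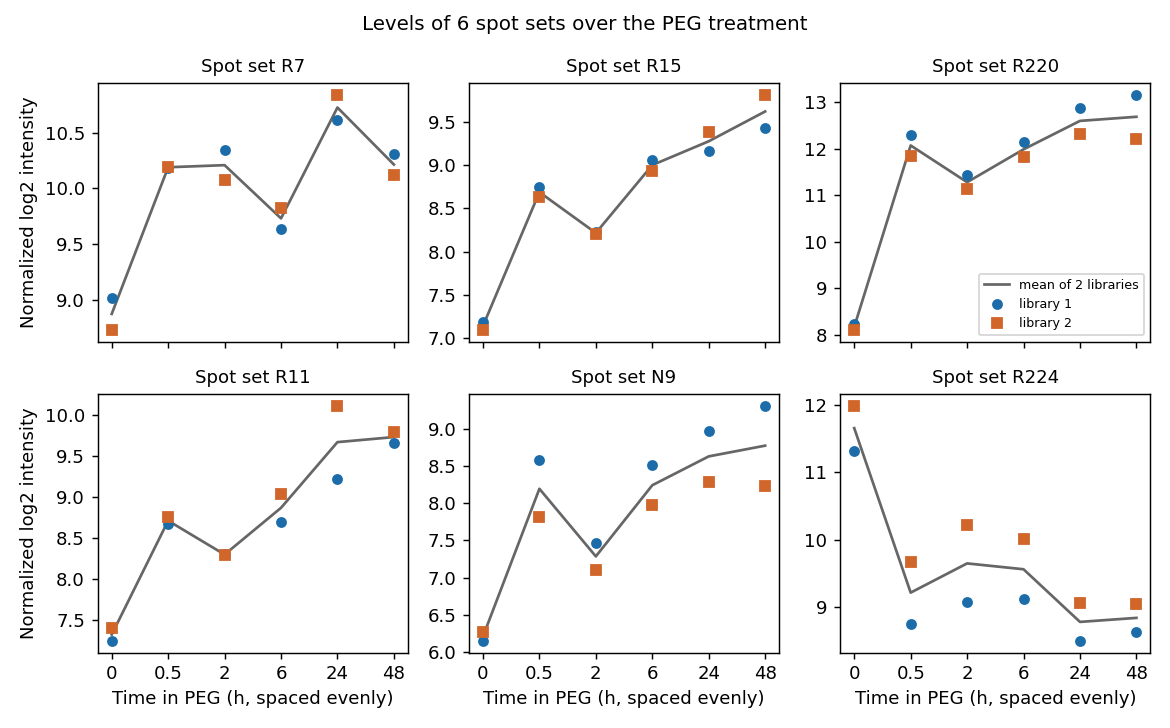
Normalized log2 intensity (y axis, scaled separately in each panel) of the 6 spot sets called at 3 or more times against time in PEG (x axis, h, spaced evenly), with circles for library 1, squares for library 2 and a line through the mean of both. R220 lay at 8.16 at 0 h and at 12.69 at 48 h, while R224 lay at 11.65 at 0 h and at 8.84 at 48 h.

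At 2 h, R220 was again the set that had risen furthest, to 11.28 ± 0.21 (SD, n = 2), a log2 change of 3.11 ± 0.33 (SE) and a fold of 8.66 (adjusted p = 0.00177). Set R7 rose from 8.87 ± 0.20 to 10.21 ± 0.19, by 1.34 ± 0.17 (SE; adjusted p = 0.00359). Set R108 fell by 0.91 ± 0.15 (SE), from 9.60 ± 0.27 to 8.69 ± 0.05 (adjusted p = 0.0133), and R64 fell by 0.76 ± 0.16 (SE), from 12.19 ± 0.07 to 11.43 ± 0.13 (adjusted p = 0.0442). The log2 change of R64 ranged from -1.34 to -0.45 over the alternatives, so its size is not settled. R224 had a log2 change of -2.002 ± 0.49 (SE) that missed the threshold (adjusted p = 0.0735) and passed it with the library number as a block (adjusted p = 5.63e-06). Of the 224 sets, 5 changed (3 rose and 2 fell) and 34 had an unadjusted p under 0.05. The fit with the block called 21 (9 rose and 12 fell), with all 5 among them. The split depended on the scaling, with 3 sets up and 6 down after median scaling, and 3 up and 0 down both without normalization and with cyclic loess. Leaving out 1 library gave 2 sets (library 1 of 0 h or library 1 of 2 h), 3 (library 2 of 0 h) or 9 (library 2 of 2 h); R108 missed the threshold without library 1 of 0 h (adjusted p = 0.0952) or library 1 of 2 h (0.114), within a range of alternatives up to 0.238, and R64 did so without any 1 of the 4 libraries (up to 0.215, and up to 0.416 over all its alternatives).

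At 6 h, R220 stood at 11.98 ± 0.24 (SD, n = 2), a rise of 3.82 ± 0.33 (SE) on the log2 scale and of 14.1 fold (adjusted p = 0.000177). N9 stood at 8.24 ± 0.38, a fitted rise of 2.04 (1.77 to 2.42 over the alternatives; adjusted p = 0.0387). R224 had a log2 change of -2.09 ± 0.49 (SE) that missed the threshold (adjusted p = 0.0698) and passed it with the library number as a block (adjusted p = 3.07e-06). In total 5 of 224 sets changed, 5 up and 0 down by limma, with 30 sets at an unadjusted p under 0.05. With the block 16 sets changed (12 rose and 4 fell), the 5 included, and median scaling gave 6 up and 1 down. The count was 2 without library 1 of 0 h or library 2 of 6 h and 3 without library 2 of 0 h or library 1 of 6 h, and N9 missed the threshold without any 1 of these 4 libraries (adjusted p up to 0.253).

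At 24 h, R220 reached 12.60 ± 0.38 (SD, n = 2), which was 4.43 ± 0.33 (SE) above 0 h on the log2 scale, a fold of 21.6 (adjusted p = 5.74e-05). N9 reached 8.63 ± 0.48, a fitted rise of 2.43 (2.09 to 2.83 over the alternatives; adjusted p = 0.0106). R224 fell by 2.87 ± 0.49 (SE) to 8.78 ± 0.40, a fold of 7.30 (adjusted p = 0.0106). Of the 224 sets, 8 changed (7 rose and 1 fell), and 36 had an unadjusted p under 0.05. Under the block 21 changed (15 rose and 6 fell), with all 8 among them. The count was 5 without either library of 0 h and 4 without library 1 of 24 h. N9 missed the threshold without library 1 (adjusted p = 0.0848) or library 2 (0.0644) of 0 h or library 1 of 24 h (0.0884), and R224 did so without library 2 of 0 h (0.0898) or library 1 of 24 h (0.0884); these were the highest adjusted p over the alternatives of both sets.

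At 48 h, R220 lay at 12.69 ± 0.68 (SD, n = 2), a rise of 4.52 ± 0.33 (SE) and a fold of 22.98 (adjusted p = 4.37e-05). N9 lay at 8.78 ± 0.76, a fitted rise of 2.57 (2.03 to 3.11 over the alternatives; adjusted p = 0.00779). R224 fell by 2.81 ± 0.49 (SE) to 8.84 ± 0.29, a fold of 7.003 (adjusted p = 0.0123). R290 was saturated at 0 h, where all 16 of its spots were at the scanner's ceiling, and its mean raw intensity was at least 2.41-fold lower at 48 h. The ceiling holds the spread of its 0 h libraries near 0, so its test is not read as evidence; it passed after quantile normalization and missed the threshold without normalization (adjusted p = 0.151), with median scaling (0.0964) and with cyclic loess (0.0761). Of the 224 sets, 8 passed the threshold (5 higher and 3 lower, the saturated R290 included), and 41 had an unadjusted p under 0.05. With the library number as a block 28 changed (21 rose and 7 fell), with all 8 among them, and the scaling moved the split to 10 up and 1 down without normalization and to 7 up and 1 down with cyclic loess. The count was 5 without library 1 of 0 h or library 2 of 48 h. R290 missed the threshold without any 1 of the 4 libraries (adjusted p up to 0.190), R224 did so without library 2 of 0 h (0.0827), library 1 of 48 h (0.0936) or library 2 of 48 h (0.0529), and N9 without library 1 of 0 h (0.0708).

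**Figure D2:**
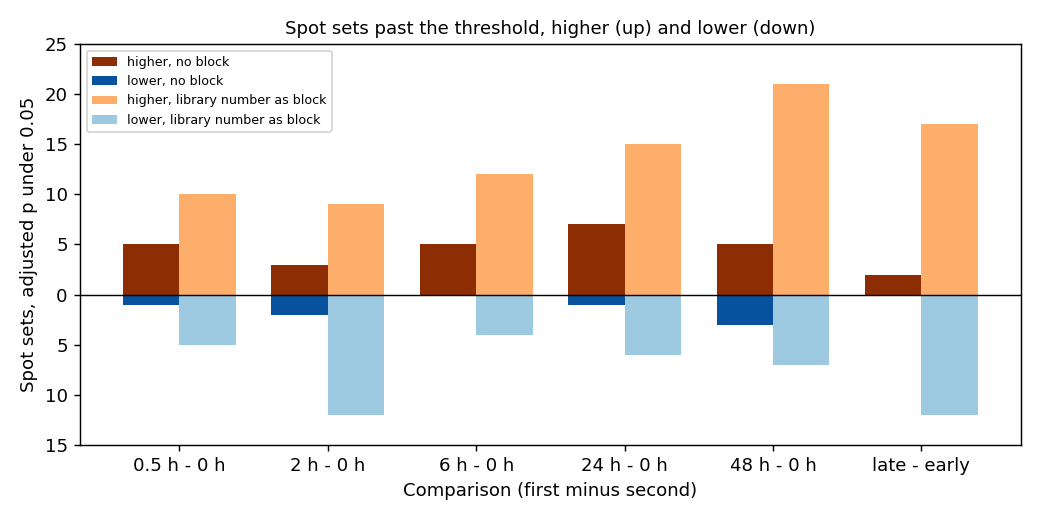
Number of spot sets with an adjusted p under 0.05 (y axis, higher above 0 and lower below 0) in each comparison (x axis), dark without a block and pale with the library number as a block. At 48 h against 0 h the bars stand for 5 higher and 3 lower sets without the block and for 21 higher and 7 lower sets with it.

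Over the 5 comparisons against 0 h, each adjusted on its own, 12 sets passed the threshold at 1 time point or more. Of these, 7 were higher and 5 lower at each time at which they passed, and 0 changed sign. But 6 of the 12 passed at 1 time only and could not change sign, and the others share the 0 h libraries between times. The 5 include the saturated R290, whose test is not read as evidence. Among the 7 is 1 set, which passed at 24 h only, that also had a spot at the ceiling on at least 1 array. Sets R220, R7 and R15 rose at all 5 times; R7 and R15 are named here after their values were seen where the rule did not name them. The rise of R15 went from 1.07 ± 0.16 (SE) at 2 h to 2.48 ± 0.16 (SE) at 48 h, and its 0 h level was within 3 times the 5th percentile of intensity on 2 of the 4 arrays (mean raw intensity 104, against 973 at 48 h), so the size of these changes depends on the offset. The rise of R7 went from 0.86 ± 0.17 (SE) at 6 h to 1.85 ± 0.17 (SE) at 24 h. R7 missed the threshold at 6 h without library 1 (adjusted p = 0.0901) or library 2 (0.148) of 0 h and without library 1 (0.101) or library 2 (0.220) of 6 h, the last being the highest over its alternatives, and R15 did so at 2 h without library 1 (0.0561) or library 2 (0.0602) of 0 h or library 1 of 2 h (0.0760), with 0.329 the highest. With the block, 47 sets changed at 1 time or more and 6 at all 5 times, 5 of them up and 1 down.

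The log2 changes of the 5 comparisons correlated across sets with a mean r of 0.791 (0.633 to 0.924 over 10 pairs of times). The comparisons share the 0 h libraries, and 100 simulations with no change at any time gave a mean r of 0.501. The mean covariance was 0.218 against 0.0545 in the simulations, a difference of 0.164. The simulated noise had the SD of the fit without the block. That SD includes the difference between library numbers, which cancels in the real contrasts, so the 0.0545 is not an exact reference. Over the 212 sets called at no time the mean r was 0.533. When library 1 of a time was set against library 1 of 0 h and library 2 of another time against library 2 of 0 h, so that no control was shared, the mean r was 0.593 and the mean covariance 0.190 over 20 ordered pairs of times; each comparison then rested on 1 library of 0 h, and this split was chosen after the data had been seen. At 24 h and 48 h, 5 sets rose in both and 1 fell in both. Independent lists of these lengths would share 0.156 and 0.0134. The simulations without any change, which share the 0 h libraries, gave 0 such sets. With no change hardly any set can pass the threshold at either time, so that 0 does not test what the shared controls add. Part of the overlap may come from the shared controls.

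The late times (24 and 48 h) were compared with the early ones (0.5, 2 and 6 h), a comparison that does not use the 0 h libraries. R11 rose by 1.07 ± 0.17 (SE) on the log2 scale, a fold of 2.11 (adjusted p = 0.0175), and R15 rose by 0.81 ± 0.10 (SE), a fold of 1.76 (adjusted p = 0.00758). R11 had means of 8.71, 8.30 and 8.87 at the early times and of 9.67 and 9.73 at the late ones, and R15 had means of 8.69, 8.22 and 9.001 and of 9.28 and 9.62. By limma 2 sets rose and 0 fell, and 22 had an unadjusted p under 0.05. With the block 29 sets changed (17 rose and 12 fell), both included. The count was 5 with median scaling, 4 without normalization, 10 with all 24 hybridizations and the library as a random block, 3 without library 2 of 2 h, 0 with cyclic loess and with first hybridizations only, and 1 without library 1 or 2 of 0.5 h, library 1 of 2 h, library 1 of 6 h or library 1 of 48 h. R11 missed the threshold without any 1 of these libraries (adjusted p 0.0586 to 0.0762) and without library 2 of 48 h (0.0774), with 0.0787 the highest over its alternatives. R11 and R15 passed in this grouping of the times, but 2 and 48 h against the other treated times gave 3 sets.

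The F test over the 5 comparisons asked which sets changed at any time. It called 6 of 224 sets, with the smallest p for R15 (adjusted p = 0.000377) and R220 (adjusted p = 0.000377). All 6 are among the 12 sets that passed in the separately adjusted comparisons, and the rest of the 12 missed the threshold here. For R224, which fell at 3 single times, the F test missed the threshold (adjusted p = 0.0743) and passed it with the block (adjusted p = 8.19e-07). At an unadjusted p under 0.05 there were 38 sets. With the library number as a block 55 sets changed, with all 6 among them.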

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

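The tests of slide position, clock time, growth and the 0 h libraries in this part were chosen after their results or related values had been seen; so were all fits of the splits with 1 group term, with or without balanced library numbers. The tests of a shared target and of the drawn splits in the fit with time points were not.

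Of 72 groups of 4 arrays of a time point tested for an array far from the others, 4 were picked out, where chance gives 3.6. The first hybridization of library 1 at 24 h had a median intensity of 407 against 194 to 226 on the other arrays of that time, and a 5th percentile of 135 against 34.0 to 45.6. A high floor was not particular to that array. The first hybridization of library 1 had a 5th percentile of 148 at 0.5 h, 140 at 2 h and 194 at 48 h, but 68.3 at 0 h and 53.0 at 6 h. Its median over the times was 138, against 50.1 for the second hybridization of library 1. In library 2 the medians were 59.8 and 31.8 for the first and second hybridizations. The second hybridization of library 1 at 0.5 h had a log2 intensity of 12.86 for R220 against 11.74 to 11.89. The second hybridization of library 1 at 0 h had 10.14 for R108 against 9.35 to 9.47.

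R11 and R15 differed between the late and the early times, by 1.07 and 0.81 on the log2 scale. Other splits of the 10 treated libraries into 4 and 6 were counted in several ways, all given here with the real split included. In the fit with time points, the only count planned, 4 of 100 drawn splits gave as many as 2 sets, with 23 the highest of the others. It was decided after the counts were seen not to exclude chance on this, since drawn splits mix times within a side, which raises the spread; the 3 others took their 4 libraries from 1 library number and follow that structure. In a fit with 1 group term and no time points the real split gave 1 set, 10 of 100 drawn splits gave as many and the highest of the others gave 22, so chance cannot be excluded there, although 8 of the 9 others were unbalanced in library number. Over the 100 splits with 2 libraries of each number in the smaller group, 2 gave as many in that fit (highest of the others 5). With the library number added, the real split gave 2 sets and 4 of these 100 gave as many (highest of the others 11). All 4 are among the 10 splits that keep both libraries of a time point together, as the real one does, so this count was not taken to exclude chance either. Among these 10, the fit with time points gave 2 sets for the real split and 3 for 2 and 48 h against the rest; with the block it gave 29, and 32 for 0.5 and 6 h against the rest. These 10 splits are too few for a share under 0.05.

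R7, R11 and R15, which rose together, lie side by side in 1 row of the array's first sub-grid. A bright region of the slide would raise the sets that touch them, but the 4 touching sets had a median log2 change of 0.0387 over the 5 comparisons (-0.41 to 0.44), against 1.54 for the 3 sets, which argues against slide position. Cross-hybridization of 1 RNA to related probes may raise all 3. It would make their differences between libraries move together, and these correlated over the 6 times by 0.766 (R7 with R11), 0.323 (R11 with R15) and -0.0178 (R7 with R15), which decides nothing. That explanation and separate responses of 3 RNAs stay open, since no probe sequences were used here.

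R220, R7 and R15 differed from 0 h at each of the 5 later times. Clock time may move small RNAs, but 24 and 48 h fall at the clock time of 0 h. The 6 sets called at 0.5 or 6 h had a median absolute log2 change of 2.45 there. That argues against clock time only if the 0 h libraries, which also served to pick these sets, were not unusual. Growth over 48 h would leave little change at 0.5 h, but R220, R7 and R15 had changed by 3.91 ± 0.33, 1.32 ± 0.17 and 1.54 ± 0.16 (SE) by then. These 3 were picked for passing at all 5 times, so a change at 0.5 h was required of them. It argues against growth as the whole cause in these 3 only, and only if the 0 h libraries were not unusual. The 8 sets called at 48 h, the saturated R290 among them, had a median absolute change of 1.47 at 0.5 h with a smallest of 2.34e-05, which belongs to a set outside the 3, so growth stays open for some of the other 5. An unusual state of both 0 h libraries would give the same pattern. The sets called at all 5 times had a median absolute late against early change of 0.81, below the 1.54 at 0.5 h. A deviation of 0 h and an effect of PEG cannot be told apart with 1 untreated time and no untreated seedlings at later times. Nor can PEG be told apart from anything else that began with the treatment.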

How the results depend on the processing

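Cyclic loess and the block combined with all 24 hybridizations were added after the data had been seen. Of 659 values recomputed for named sets past the threshold, 568 stayed past it, 91 kept their direction and missed it, and 0 reversed; R220 passed at each time against 0 h under each alternative run (adjusted p at most 0.0264). That 0 of the 659 reversed was largely fixed in advance. The library number as a block, the other moderation and the fits of only the libraries compared leave the log2 change unaltered. Leaving out a library cannot reverse a change against 0 h, since the libraries of these sets did not overlap. Of 118 counts of changed sets under alternatives other than leaving out a library, 83 were within 1.5 times of the reported one, 25 were higher and the other 10 lower. Both totals include the setting without a filter on dim sets, which repeats the main fit. They also include the deposited table, which repeats plain background subtraction. The shares that stayed alike are therefore overstated. The cause was not tested unless stated.

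With the replicate block the counts at 0.5, 2, 6, 24 and 48 h, late against early and in the F test were 15, 21, 16, 21, 28, 29 and 55; the block removes a difference between library numbers, and the median fitted SD went from 0.22 to 0.17. Combined with all 24 hybridizations they were 18, 36, 25, 27, 36, 32 and 66. All 24 hybridizations with the library as a random block and no library number gave 11, 10, 15, 20, 10 and 27 from 2 h on. Median scaling gave 9 at 2 h, 5 late against early and 10 in the F test. No normalization gave 3 at 2 h and 4 late against early, and cyclic loess 3 and 0. The median over spots gave 8 at 2 h. First hybridizations only gave 3 at 0.5 h, 3 at 2 h and 0 late against early; second ones only gave 2 at 6 h and 5 at 48 h. With only the libraries compared in the fit, and so fewer degrees of freedom, 1 set passed at 2 h and 5 at 24 h.

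Leaving out 1 library gave 3 to 4 sets at 0.5 h, 2 to 9 at 2 h, 2 to 3 at 6 h, 4 to 7 at 24 h, 5 to 8 at 48 h, 1 to 3 late against early and 4 to 7 in the F test; the lone library left was assumed to vary like the others. Without normalization the median log2 change of all sets was 0.17 at 0.5 h, 0.11 at 2 h and 0.20 at 48 h, and after median scaling it was -0.12 at 2 h and -0.14 at 48 h. The filter on dim sets removed none, so that alternative tested nothing. Scaling on control probes, the miRNA lists and a block for slide or scan were not run, for lack of probe names and of a shared scan. Background near 0 in the files leaves the limit set by signal over background unknown.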

Other observations

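All tests in this part were planned before their own values were seen, after the likeness of the differences between libraries had been noticed. Library 1 and library 2 differed alike at all 6 times. With time in the fit, 83 of 224 sets differed between the library numbers, 48 higher and 35 lower in library 2. In the same fit 47 sets changed with time at 1 time or more. These counts do not show which moved more sets. The library numbers were compared as 6 libraries against 6, and each time against 0 h as 2 against 2. Chance differences between single hybridizations would not repeat, but the difference seen on first hybridizations correlated with that on second ones by a median of 0.503 (0.274 to 0.687 over the 6 times). An intensity-dependent scale left by the normalization would vanish with the trend, but after removing a smooth trend on intensity the lowest correlation between times was 0.487. Both values argue against these explanations. A shared origin of libraries with 1 number, in the seedlings or in the library preparation, may account for it, and the labels do not say which.

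The files give code R105 at 2 places. The numbering leaves out 1 code at the second place, so it is not known that both hold 1 probe. The second was brighter than the first on 24 of 24 arrays, by 1.10 ± 0.41 on the log2 scale (SD over arrays; 0.38 to 2.05).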
